A study of Homo sapiens with 6 samples.

How the data were processed

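Argonaute (Ago) HITS-CLIP was performed on primary human umbilical artery endothelial cells (HUAEC, 3 samples) and umbilical vein endothelial cells (HUVEC, 3 samples). In this assay RNA is crosslinked to protein, the Ago complexes are pulled down with an antibody, and the bound RNA is sequenced as short tags. The antibody was a pan-Ago antibody and cells were crosslinked after 3 passages, per the labels' protocols.

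For each cell type a list of peaks and a list of deletion sites were used, 4 files in all. Each list combined the 3 samples of its cell type, per the file names, so values per sample were not analysed here and no difference between cell types could be set against the spread of replicates. The sample titles carry a letter, E or L, whose meaning is not given in the sources used here, so a list may mix 2 kinds of sample. The submitters' processing notes name STAR 2.4.1a, Novoalign and the build hg19 without saying which step each served. The peak caller is named only in the file names (Piranha), and its version and settings are not given in the sources used here.

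The deposited peak lists give a coverage signal for each peak, in tags per 30-nt bin, with no normalisation stated. Every start and end was a multiple of 30. The signal was a whole number in all 1321 HUAEC and all 2442 HUVEC peaks of 1 bin. In wider peaks it was a mean over bins: signal times number of bins was whole within 0.02 in 50 of 51 HUAEC and 94 of 95 HUVEC peaks. In 1-bin peaks of a list, the deposited p-value had 1 value per signal and never rose with the signal; wider peaks did not follow that order. The p-value at a given signal was higher in HUVEC at all 181 signals that occurred in 1-bin peaks of both lists, with a median ratio of 269704. A peak of 200 tags had a p-value of 1.77e-09 in HUAEC and 0.000344 in HUVEC, so p-values were not compared between the lists. The exception is the planned p cuts among the alternatives, which fall on unlike scales.

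The deposited deletion lists give counts for each site, per the file headers: the unique tags over the base and the tags that carry a deletion there. Deletions arise where reverse transcriptase passes a crosslinked base. Each site also has a false discovery rate, used here as the deposited q-value, and a rate of 0.05 or below counted as past the rate.

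Peaks were compared by overlap of at least 1 nt on the same strand. Overlap by chance was estimated by moving every HUAEC peak by a random multiple of 30 nt between 1 and 10 kb to either side, with 1000 draws. The planned re-placement within annotated exons was not run, because no annotation of hg19 was used here. The shifts do not keep a peak within its RNA, so they do not give the chance overlap among transcribed positions. The script was tested on simulated data first: of 200 planted shared peaks in a list of 1372, 200 were recovered, and at most 4 overlapped after random shifts. The planted peaks were exact copies and all other simulated HUVEC peaks were moved out of reach. Partial overlap and the chance rate of a full list were therefore not checked.

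Overlapping peaks were joined into shared sets, and the tags of a set (signal times bins, summed) were compared as a log2 ratio of HUVEC over HUAEC, as a description of 2 lists that were not normalised to each other. Correlations are across peaks, which are not independent replicates, with 100000 permutations. Peaks within 10 kb on a strand were joined into loci. Runs are neighbouring deletion sites on a strand joined into 1. Shares carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting of peaks or sites only, since tags without molecular identifiers are not independent molecules. Sites inside and outside peaks were compared with a two-sided Fisher's exact test within a list, which treats neighbouring sites as independent. No p-value is given between cell types.

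The regions named are the 10 highest peaks of each list, the 10 highest peaks of each list without an overlapping peak in the other, and the 5 shared sets with the largest ratio each way among those with at least 50 tags in 1 of the lists, all without mitochondrial and X peaks. That rule was fixed before the data were examined, for genes, with the highest set limited to exonic peaks of protein-coding genes. It was applied to peaks because no gene could be assigned. The fixed rule left out XIST, and leaving out all of chromosome X was not part of it. Dense loci and mitochondrial peaks were chosen after their values were seen. Chromosome Y was left out of every value, no peak of chromosome X is named or drawn singly, and no single deletion site is given, since a deletion can be a donor's own variant. Positions count from 1 on hg19. Gene names, gene parts, seed matches, microRNA loci and gene lists are not analysed here, because the reference table at hand was of another build.

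Alternatives fixed before the data were examined covered stricter p-values, tag minimums, the overlap that counts as shared, strand, scaling of the ratio, and thresholds on deletion sites. Others were added after the data were seen, among them a common tag floor, 200 and 500 tags per bin, shared sets with identical bins, no mitochondrial peaks, peaks within 1000 nt and sites in classes of depth. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and drawn with matplotlib 3.10.9.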

Results

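Ago HITS-CLIP was used to compare where Ago, the protein that carries microRNAs to target RNAs, sat on RNA in arterial and venous endothelial cells. HUAEC and HUVEC come from the umbilical artery and vein. Each cell type had 3 samples, combined into 1 list of peaks and 1 list of deletion sites. The HUAEC list held 1372 peaks over 44130 nt with 334331 tags, or 7.58 tags per nt. The HUVEC list held 2537 peaks over 81420 nt with 734646 tags, or 9.02 tags per nt. Library totals were not used here, so the sequencing depth is unknown. The lists give no spread between samples, and the intervals below cover counting only.

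Both cell types shared their summits. Heights are the authors' values, not normalised between lists. Outside the mitochondrial and X chromosomes, the highest HUAEC peak was on chromosome 16, plus strand, at 33963901 to 33963930, with 5052 tags per bin, and it had 8002 in HUVEC. The highest HUVEC peak, on chromosome 17, minus strand, at 33478141 to 33478200, had 8074.5 tags per bin against 2894 in the wider HUAEC peak that starts at the same base. These are means over unlike widths. Summed over the whole shared set, 33478141 to 33478350, HUVEC had 21610 tags and HUAEC 20261. Chromosome 12, minus strand, 127650601 to 127650630 had 3951 tags per bin in HUAEC and 6174 in HUVEC. Chromosome 8, minus strand, 56755201 to 56755230 had 3762 and 6422. Of the 10 highest peaks in each list outside the mitochondrial and X chromosomes, 8 were among the 10 highest of the other. All 10 of each list overlapped a peak of the other.

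A pair of further chromosome 16 plus-strand peaks, starting at 33963601 and 47538721, had 2181 tags per bin each in HUAEC, and 2416 and 2409 in HUVEC. Whether the same tags were counted at both places was not tested. Chromosome 2, minus strand, 133012921 had 2171 in HUAEC and 2935 in HUVEC, and chromosome 12, minus strand, 34372621 had 2267 and 3048. On chromosome 1, minus strand, a HUAEC peak at 91852771 to 91852920 had a mean of 2343 tags per bin, and the HUVEC peak from the same base, which ran on to 91853130, had 1972. Chromosome 17, plus strand, 36646681 had 1714 and 1650. Among the highest HUVEC peaks, chromosome 11, minus strand, 62609191 had 4217 tags per bin against 1129 in HUAEC, and chromosome 20, minus strand, 26190451 had 2694 against 695. Ranked by total tags over their width instead, with all chromosomes but Y, the 10 leading peaks held 21.8% of the peak tags in HUAEC and 14.8% in HUVEC.

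Most peaks were low and 1 bin wide. The median peak had 127 tags per bin in HUAEC and 153 in HUVEC. The lowest listed had 94 and 115. Peaks of 30 nt made up 96.3% of each list. At least 200 tags per bin were reached by 252 HUAEC and 725 HUVEC peaks, and at least 500 by 61 and 158.

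The artery and vein lists shared most peaks of at least 500 tags per bin and few of their low ones. In all, 339 of 1372 HUAEC peaks (24.7%, 22.4 to 27.1) overlapped a HUVEC peak, and 332 of 2537 HUVEC peaks (13.1%, 11.8 to 14.5) overlapped a HUAEC peak. Of HUAEC peaks with at least 500 tags per bin, 58 of 61 were shared (95.1%, 86.3 to 99.0). Of those below the HUVEC floor of 115 tags, 8.46% were shared (6.19 to 11.2). In HUVEC, 126 of 158 peaks with at least 500 tags per bin were shared (79.7%, 72.6 to 85.7), against 1.47% (0.708 to 2.69) of those with 115 to 130 tags. From 300 to below 500 tags, 74.2% of HUAEC and 35.6% of HUVEC peaks were shared, and from 200 to below 300 tags 53.6% and 16.3%. After random shifts within 10 kb a mean of 13.6 HUAEC peaks overlapped, and at most 26 (one-sided permutation p = 0.001, the smallest that 1000 draws can give). A shifted peak can leave the RNA that held it. The shifts therefore cannot tell shared positions within RNAs from RNAs present in both cell types. A peak missing from a list lay below its floor or was not called, which does not show absence of binding.

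**Figure D1:**
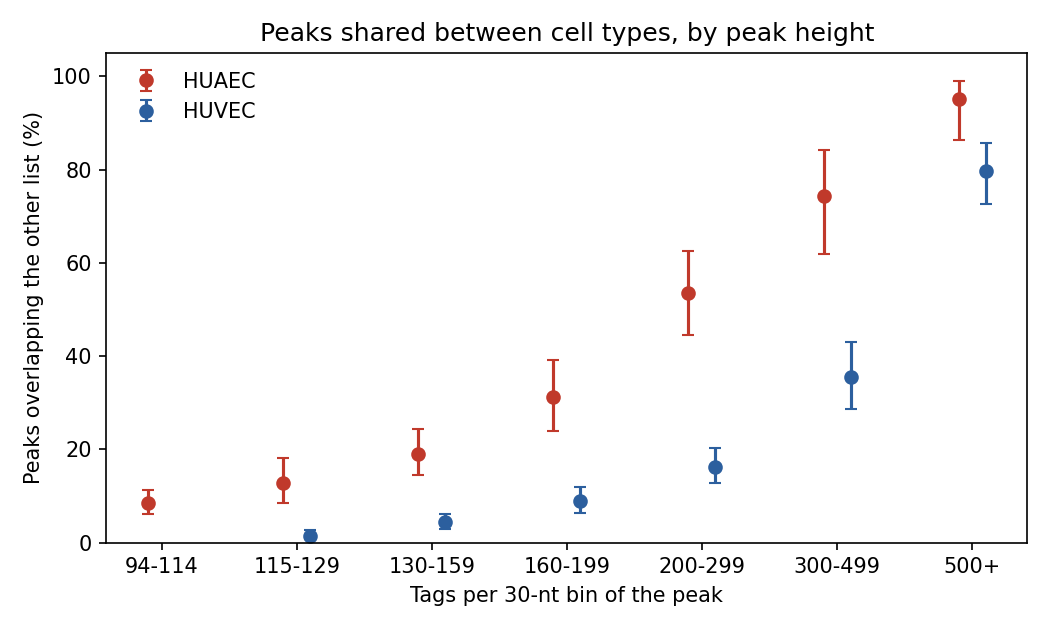
Share of peaks (%) that overlap a peak of the other list, by tags per 30-nt bin, for HUAEC (red) and HUVEC (blue). Bars are exact 95% binomial intervals over peaks; the share rose from 8.46% to 95.1% in HUAEC and from 1.47% to 79.7% in HUVEC.

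Of peaks with at least 500 tags per bin, 3 in HUAEC and 32 in HUVEC had no overlapping peak in the other cell type. The highest in HUAEC was at chromosome 10, plus strand, 75504541 to 75504570, with 847 tags per bin. Chromosome 1, plus strand, 93828031 and chromosome 11, minus strand, 65272981 had 572 each, and chromosome 18, plus strand, 77662921 had 466. The highest in HUVEC was at chromosome 19, plus strand, 50000971 to 50001000, with 991 tags per bin. Chromosome 9, plus strand, 136217701 had 873, chromosome 6, minus strand, 27181591 had 805, and chromosome 6, plus strand, 144537721 and 44221471 had 775 and 766. The other named HUAEC peaks lay between 345 and 427 tags per bin, and the other HUVEC ones between 692 and 723. A peak of the other list lay within 10 kb on the same strand for 1 of the 10 HUAEC peaks and 4 of the 10 HUVEC peaks.

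Tags in shared peaks rose together in both cell types. Across 330 shared sets, log2 tags correlated with Pearson's r = 0.778 and Spearman's rho = 0.630 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give). Without the 2 sets farthest from the HUAEC median, r was 0.755. HUVEC had more tags in 266 sets and fewer in 63, with a median log2 ratio of 0.73 (SD 0.96 across sets), or 1.66-fold. In the 277 sets with identical bins in both lists it was 0.57. That direction reversed with scaling by the tags in all peaks of each list, whose ratio was 2.20: the median became -0.40, with 111 sets higher in HUVEC and 219 lower. No direction between the cell types can be read from these sums, which were not normalised between lists.

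The shared regions farthest from the median ratio lay on several chromosomes. A bin called in 1 list alone counts as 0 tags in the other, so sets of unequal width overstate the ratio. With 1 bin of 30 nt in each list, chromosome 11, plus strand, 65272681 had 917 tags in HUVEC and 94, the HUAEC floor, in HUAEC. The ratio was 9.76 against the median of 1.66, with no interval because tags are not independent molecules. Chromosome 1, minus strand, 161397841 had 1002 and 103. In 3 further sets HUVEC covered more bases: chromosome 7, plus strand, 139025431 to 139025490 had 1832 tags over 60 nt in HUVEC and 173 over 30 nt in HUAEC. Chromosome 1, plus strand, 94313101 to 94313190 had 1910 over 90 nt and 182 over 30 nt, and chromosome 12, plus strand, 98897281 to 98897340 had 958 over 60 nt and 131 over 30 nt. In the other direction, chromosome 1, plus strand, 45242551 to 45242580 had 767 tags in HUAEC and 128 in HUVEC, a ratio of HUAEC over HUVEC of 5.99. Chromosome 7, plus strand, 148638571 to 148638630 had 2055 over 60 nt in HUAEC and 570 over 30 nt in HUVEC, and chromosome 17, plus strand, 36666541 had 391 and 120. Chromosome 6, minus strand, 6002641 had 423 and 176, and chromosome 2, plus strand, 183581101 had 324 and 146.

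**Figure D2:**
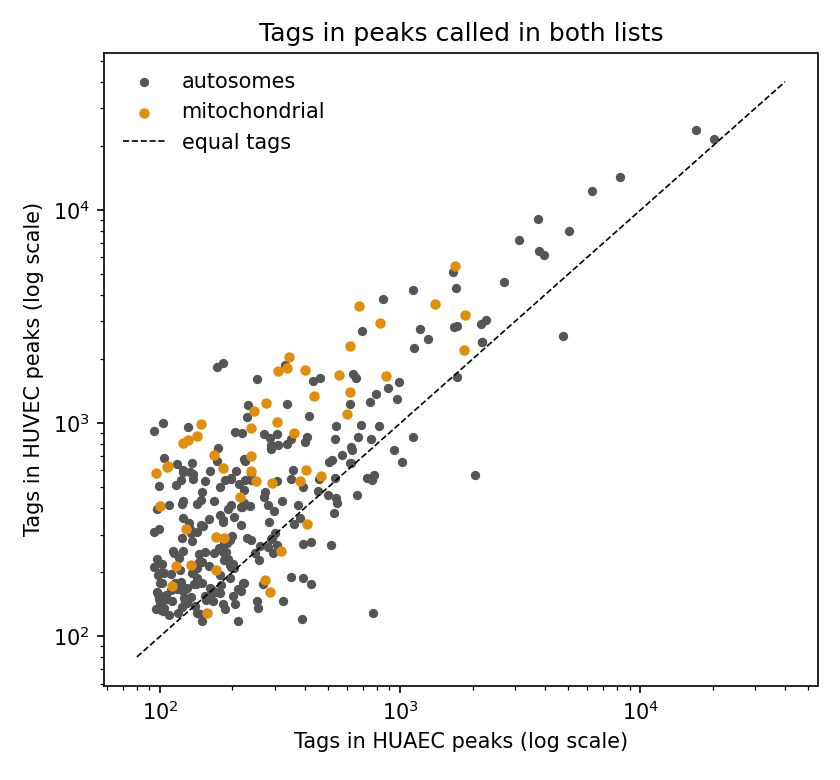
Tags in HUVEC peaks against tags in HUAEC peaks (both log scales) for the shared sets without chromosome X, with mitochondrial sets in orange and a dashed line of equal tags. Pearson's r was 0.778 over all 330 sets, and 266 sets lay above equality before scaling.

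Some stretches held many peaks of both cell types. Outside the mitochondrial and X chromosomes, the locus with the most peaks was on chromosome 15, plus strand, 39873301 to 39890820, with 22 HUAEC and 50 HUVEC peaks, of which the highest had 351 and 843 tags per bin. These covered 690 nt in HUAEC and 1620 nt in HUVEC, with 3339 and 12536 tags, or 4.84 and 7.74 tags per nt. Chromosome 2, minus strand, 133010701 to 133015230 held 12 HUAEC and 13 HUVEC peaks. Chromosome 11, plus strand, held 5 and 12 peaks at 65191411 to 65212560, and again 5 and 12 at 65268181 to 65273070. Chromosome 16, plus strand, 33963061 to 33965580 held more HUAEC than HUVEC peaks, 10 against 6. The HUVEC peaks there were wider, covering 570 nt with 20016 tags, against 510 nt with 12118 tags in HUAEC. Chromosome 7, plus strand, 100770421 to 100782420 held 2 and 13.

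Of 2699 loci over both lists, 340 held peaks of both cell types, 809 of HUAEC alone and 1550 of HUVEC alone. Of the 51 loci with at least 5 peaks in both lists together, a choice that favours loci with both, 47 held both, 4 HUVEC alone and 0 HUAEC alone. The 4 with HUVEC peaks alone were chromosome 12, plus strand, 6643981 to 6647430 with 7 peaks, chromosome 6, plus strand, 44218801 to 44221500 with 6, and chromosome 19, plus strand, 39200071 to 39220920 and chromosome 1, plus strand, 86047711 to 86048910 with 5 each.

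**Figure D3:**
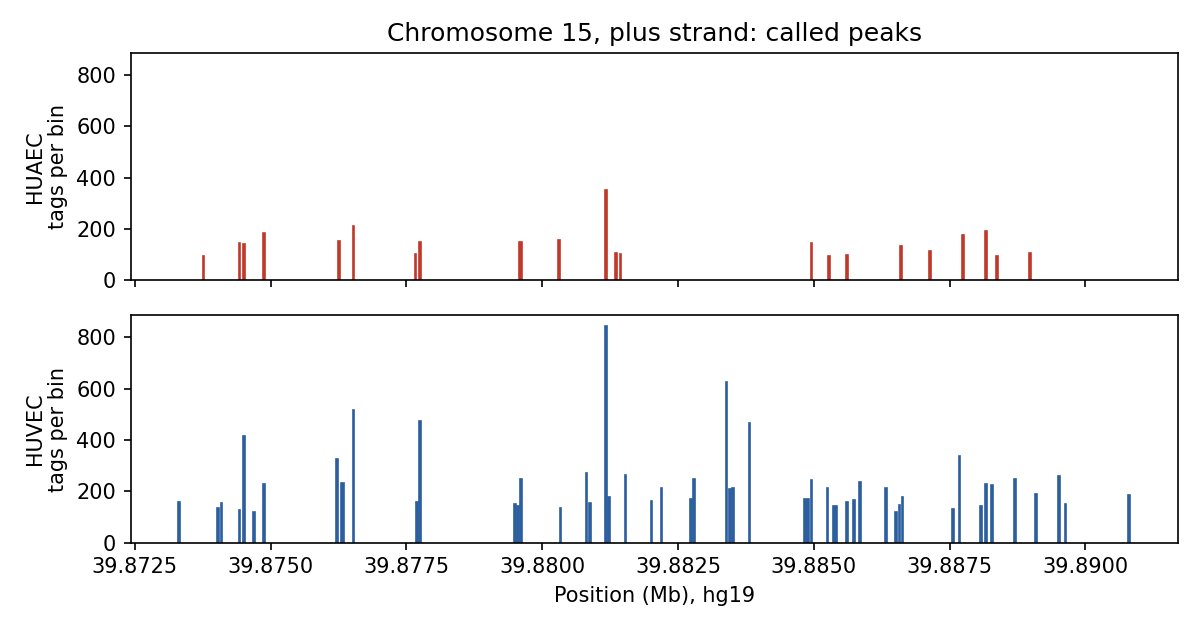
Called peaks on chromosome 15, plus strand (position in Mb, hg19), as bars with height in tags per bin, for HUAEC (red) and HUVEC (blue). There were 22 HUAEC and 50 HUVEC peaks, reaching 351 and 843 tags per bin.

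The mitochondrial chromosome carried 71 HUAEC peaks (5.17% of the list) and 111 HUVEC peaks (4.38%). They held 7.17% of HUAEC and 9.93% of HUVEC peak tags, over 2610 and 4620 nt, or 9.18 and 15.8 tags per nt. More of them were shared than elsewhere: 54 HUAEC peaks (76.1%) and 51 HUVEC peaks (45.9%). Their median height was 192 tags per bin in HUAEC and 278 in HUVEC, above that of all peaks, and sharing was not compared at equal height. Summits at 3301 to 3330 (1864 tags per bin in HUAEC, 3208 in HUVEC) and 3241 to 3270 (1845 and 2196) were high in both. That at 12271 to 12300 had 672 and 3530. The HUVEC bin at 7681 to 7710 had 2943, and the HUAEC peak over it, at 7651 to 7710, had a mean of 412.5. The median log2 ratio was 1.38 over the 51 mitochondrial sets and 0.60 over the 279 others, with bins called in 1 list alone included. Among sets with identical bins it was 1.08 for 32 mitochondrial sets and 0.55 for 245 others, both below the log2 ratio of all peak tags (1.14).

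**Figure D4:**
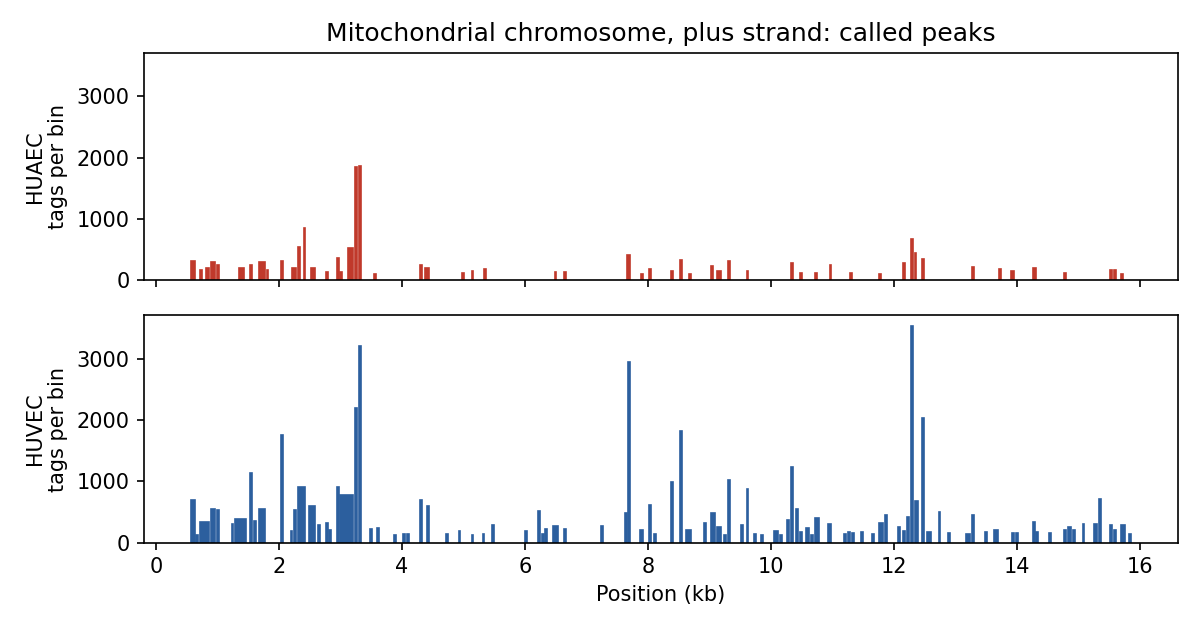
Called plus-strand peaks on the mitochondrial chromosome (position in kb), as bars with height in tags per bin, for HUAEC (red) and HUVEC (blue). The summits at 3301 and 12271 had 1864 and 672 tags per bin in HUAEC, and 3208 and 3530 in HUVEC.

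The 2 pooled lists differed in the strand of their peaks taken as a whole. In HUAEC 804 of 1372 peaks lay on the plus strand (58.6%, 55.9 to 61.2), and in HUVEC 1793 of 2537 (70.7%, 68.9 to 72.4). Plus-strand peaks outnumbered minus-strand peaks on 17 of 22 autosomes in HUAEC and on all 22 in HUVEC. Among peaks of 1 list alone the share was 55.8% in HUAEC and 71.2% in HUVEC. Among peaks with at least 500 tags per bin it was 65.6% (52.3 to 77.3) and 67.1% (59.2 to 74.3). Of these peaks 58 of 61 in HUAEC and 126 of 158 in HUVEC were shared, which requires the same strand. The 2 shares therefore rest largely on the same regions, and no conclusion is drawn from their closeness. Deletion sites lay near evenly on the strands, with 6656 of 12905 on the plus strand in HUAEC (51.6%, 50.7 to 52.4) and 13917 of 27840 in HUVEC (49.4 to 50.6%). These intervals count neighbouring bases separately. With runs counted once and no mitochondrial sites, the shares were 50.8% (49.7 to 52.0) and 49.6% (48.8 to 50.4), so no difference was detectable. The share of a list's peaks on each of 23 chromosomes had overlapping intervals in the lists for every chromosome.

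**Figure D5:**
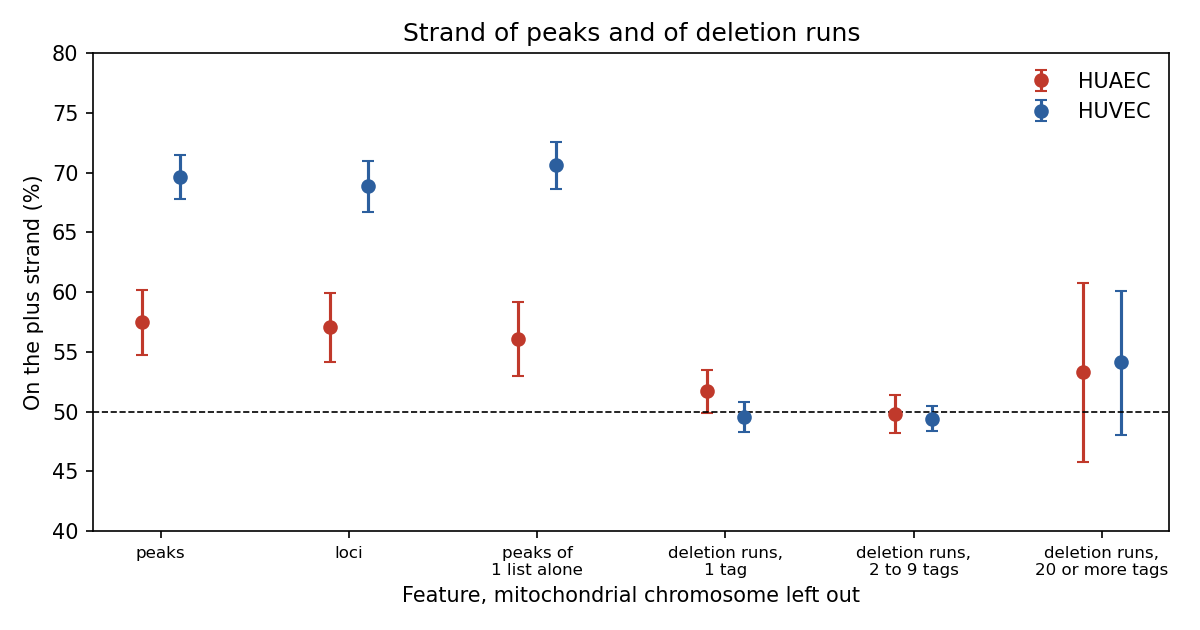
Share on the plus strand (%) of peaks, loci, peaks of 1 list alone and deletion runs by tags over the run, without the mitochondrial chromosome, for HUAEC (red) and HUVEC (blue). Bars are exact 95% intervals, the dashed line is 50%, and the axis starts at 40%; peaks stood at 57.5% in HUAEC and 69.7% in HUVEC.

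Deletion sites, which can mark bases crosslinked to Ago, were more numerous in the vein list. HUAEC had 12905 listed sites and HUVEC 27840, of which 4484 and 10562 passed the false discovery rate of 0.05. Most were thinly covered: 45.8% of HUAEC and 43.0% of HUVEC sites lay under 1 unique tag. Among sites past the rate, 60.1% in HUAEC and 52.6% in HUVEC had 2 tags, and the deletion was in all tags of 73.1% (71.7 to 74.4) and 73.4% (72.6 to 74.2). Every site past the rate with 2 tags had the deletion in both. With at least 3 tags the share was 32.5% and 43.9%. Counting neighbouring sites once left 2822 runs in HUAEC and 6661 in HUVEC. At the same base and strand, 1875 sites were listed in both cell types and 313, in 168 runs, passed the rate in both.

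Few deletion sites lay in peaks of either cell type. In HUAEC 1.29% of sites past the rate (0.984 to 1.67) lay in a peak, against 2.79% of the others (odds ratio 0.456, Fisher's exact p = 1.76e-08). In HUVEC the shares were 1.29% (1.08 to 1.52) and 2.92% (odds ratio 0.433, Fisher's exact p = 5.26e-20). That direction reversed at a false discovery rate of 0.001 or below, with odds ratios of 2.38 in HUAEC and 1.43 in HUVEC. Depth was not held constant in either comparison, so neither shows a direction at equal depth. Sites past the first rate were also compared with the others in classes of depth. Under 3 to 9 tags the odds ratio was 0.523 in HUAEC (Fisher's exact p = 0.00761) and 0.318 in HUVEC (Fisher's exact p = 3.09e-13). Under 10 or more tags it was 0.832 in HUAEC (Fisher's exact p = 0.492) and 0.598 in HUVEC (Fisher's exact p = 0.00047). Under 20 or more it was 1.43 in HUAEC (Fisher's exact p = 0.362) and 0.476 in HUVEC (Fisher's exact p = 0.000429). The share in peaks rose with depth, from 0.101% of HUAEC and 0.0418% of HUVEC sites under 1 tag to 43.3% and 48.3% of sites under at least 20 tags.

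Seen from the peaks, 132 HUAEC peaks (9.62%, 8.11 to 11.3) and 299 HUVEC peaks (11.8%, 10.6 to 13.1) held a listed deletion site. Shared peaks held one more often than others, at 24.8% against 4.65% in HUAEC and 30.7% against 8.93% in HUVEC, though shared peaks were also higher and the comparison was not made at equal height. In peaks with a site, the tags per bin exceeded the unique tags over the deepest site by a median of 12.1 times in HUAEC and 17.7 times in HUVEC.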

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

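Settings with 200 or 500 tags per bin, identical bins, the common floor, no mitochondrial peaks, 1000 nt, loci, runs and depth classes were chosen after the data were seen. Of 67 alternative values for 12 results, 7 changed nothing (the minimums of 20 and 50 tags removed no peak). A further 23 kept their direction and side of the threshold and were classed as the same. Of the others, 32 were classed as moved, 1 no longer passed its threshold and 4 reversed. The limit between same and moved differed by kind of result. A fall from 2537 to 1894 HUVEC peaks, with those within 10 kb counted once, was classed as the same.

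With p at or below 0.001, HUVEC kept 1180 peaks and HUAEC all 1372, since its highest p-value was 1.22e-05. At or below the median HUAEC p-value, HUAEC kept 694 and HUVEC 197. Which list is longer under a p cut follows from the unlike p-value scales. At equal raw heights HUVEC stayed longer: 2537 peaks against 864 in HUAEC at 115 tags, the HUVEC floor, and 725 against 252 at 200. Heights were not normalised. The 725 are fewer than all 1372 HUAEC peaks (at least 94 tags), so scaling could reverse this.

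The HUAEC share of shared peaks was 21.8% with p at or below 0.001, 34.3% with the common floor, 61.9% with 200 tags per bin, 21.9% without mitochondrial peaks, 27.8% within 50 nt and 33.9% within 1000 nt. The HUVEC share was 24.7%, 11.4%, 21.2%, 11.6%, 15.8% and 23.5% in the same order. It exceeded the HUAEC share with p at or below 0.001, a cut that removed HUVEC peaks alone, and was below it in the others.

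The median log2 ratio reversed to -0.40 when scaled by the tags in all peaks, by the construction of that scaling. The plus-strand share with 200 tags per bin was 63.1% in HUAEC (56.8 to 69.1) and 67.7% in HUVEC (64.2 to 71.1), and with 500 it was 65.6% and 67.1%. The intervals overlap at both.

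Deletion sites fell to 893 in HUAEC and 3252 in HUVEC at a rate of 0.001 or below, and to the same numbers (893 and 3252) with at least 3 deletion tags. They fell to 380 and 1038 with the deletion in under 50% of tags, 33 and 120 with at least 20 tags, and 2822 and 6661 as runs. The odds ratio of lying in a peak reversed at a rate of 0.001 or below, to 2.38 in HUAEC and 1.43 in HUVEC. In HUAEC it was 0.832 (Fisher's exact p = 0.492) with 10 or more tags and reversed to 1.43 (exact p = 0.362) with 20 or more, past no threshold in either. In HUVEC it stayed below 1 in every depth class. Depth was not held constant in the comparison of all sites, nor in any at 0.001. Sites under 1 or 2 tags (5912 and 3285 in HUAEC, 11970 and 6705 in HUVEC) far outnumbered the sites past that rate. Most of them therefore fell among the other sites, and at most 0.164% of any of these classes lay in a peak. The reversal at 0.001 can follow from depth and cannot be read as a change of direction. The cause was not tested further.

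Leaving out a replicate could not be done, and no paired analysis was possible because the lists pool the samples of each cell type. The alternatives for genes, gene parts, seed matches and gene lists were not run.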

Other observations

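Tests on opposite-strand sites, deep deletion runs, peaks with at least 500 tags, HUVEC peaks in neighbouring bins and sites with at least 3 tags were chosen after the result was seen. Limits were also reset after values were known. For deep runs a first limit, an interval wholly below 50%, had left both cell types undecided. For HUVEC peaks with at least 500 tags a first limit of 90% shared had counted against the floor.

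More peaks lay on the plus strand than on the minus strand, most clearly in HUVEC. A few crowded loci do not account for it, since loci counted once and without mitochondrial peaks were on the plus strand in 57.1% of HUAEC and 68.9% of HUVEC cases, with intervals above 50%. Nor do tags of both strands counted together, in the plus-strand peaks that held deletion sites. There 4.69% of HUAEC and 3.87% of HUVEC sites lay on the minus strand. In minus-strand peaks, 12.6% of HUAEC and 2.51% of HUVEC sites lay on the plus strand. Only 9.62% of HUAEC and 11.8% of HUVEC peaks held a listed site, so most peaks were not covered. Under at least 20 unique tags, 54.1% of HUVEC deletion runs were on the plus strand (48.1 to 60.1), below the 67.8% lower bound for HUVEC peaks, while the HUAEC share of 53.3% (45.8 to 60.8) reached the range of its peaks, so there the peaks and the unique tags cannot be told apart. A candidate explanation left open is repeated tags or a peak-calling step that treated the strands unequally, and a difference between artery and vein was not tested.

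Few peaks were shared. For HUAEC, peaks close to the floor of the HUVEC list are a candidate explanation, since 95.1% of peaks with at least 500 tags per bin were shared, though 1 of the 3 unshared ones exceeded the HUVEC floor by more than the largest ratio of HUAEC over HUVEC among shared sets with identical bins, 5.99. For HUVEC 79.7% were shared, which leaves it undecided: 0 of the 32 unshared peaks exceeded the HUAEC floor by more than the largest ratio the other way, 10.6. The highest of them, with 991 tags per bin, fell just short of the 994 that this ratio sets. That count therefore depends on the most extreme shared set. Calling the same locus in neighbouring bins stayed undecided for HUAEC, whose share within 1000 nt was 1.37 times the overlapping share, between the limits of 1.1 and 1.5 set beforehand; for HUVEC the ratio was 1.80, past 1.5, so this may account for part of it, though crowded loci were not set apart. A difference between artery and vein cells stays open and untested.

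Most deletion sites past the false discovery rate lay in all of their tags. Counting a deletion of several bases once left the share at 72.7% in HUAEC and 72.3% in HUVEC, so that is not the cause. With at least 3 tags it was 32.5% in HUAEC and 43.9% in HUVEC. Every site past the rate under 2 tags had the deletion in both, so leaving these sites out had to lower the share. The majority rested on them, which is a matter of counting and not the outcome of a test. No biological explanation was tested.

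Runs of deletion sites had an excess at 6 bases. In HUAEC there were 71 runs of 5 bases, 179 of 6 and 32 of 7, and in HUVEC 149, 362 and 111. In runs of more than 1 base, tags and deletion tags were equal at every base in 90.4% of HUAEC and 90.6% of HUVEC runs.

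Recurrence of sites past the rate was uneven. Of sites under 3 to 9 tags with the deletion in all of them, 343 of 582 in HUAEC (58.9%) were listed in HUVEC, and 115 of 2201 in HUVEC (5.22%) were listed in HUAEC. Of those with the deletion in some tags, 22.8% and 7.71% were listed in the other. The asymmetry was smaller under 10 or more tags, at 59.3% in HUAEC and 27.4% in HUVEC, and under 2 tags, at 9.58% and 4.23%. Whether the lists share donors or tags is unknown, and neither that nor alignment was tested as the source of the asymmetry.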
